A study of Arabidopsis thaliana with 4 samples.

How the data were processed

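Total RNA of 5-day-old Arabidopsis thaliana seedlings was sequenced in 4 libraries, 2 of wild-type Col-0 and 2 of the HBI1-overexpressing line, per the labels' protocols after extraction with the Spectrum Plant Total RNA Kit and from barcoded libraries made with a TruSeq RNA kit. Groups and library numbers were taken from the labels. Replicates were treated as separate samples as the labels number them.

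The authors deposited whole-number read counts per gene for each library, for 33518 loci, without normalization. Per the submitters' processing notes, the tools TopHat and DESeq and the genome build TAIR10 were used; their versions, the read counter and its strand setting are not given in the sources used here. Each count file ends with rows that belong to no gene (reads with no feature, ambiguous reads, reads not aligned and the like), which were left out of library sizes and tests; they held 13.7%, 13.7%, 13.5% and 13.2% of the reads of Col-0 libraries 1 and 2 and HBI1-Ox libraries 1 and 2. Reads from a gene and from an overlapping gene on the opposite strand may therefore not be told apart, and how reads of near-identical genes were assigned is not given in the sources used here. The authors also deposited a table of log2 fold changes of HBI1-Ox over Col-0; how its genes were chosen is not given in the sources used here. Its log2 values equalled the ratio of group means of counts divided by DESeq2 size factors within 0.00556.

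Reads on genes per library ranged from 10785178 to 19647745. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 20320. Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, HBI1-Ox against Col-0, all 4 libraries, 2 residual degrees of freedom, no block), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The biological coefficient of variation was 8.16%. CPM values were computed on the TMM-scaled library size. Standard errors of log2 changes are the absolute change divided by the square root of the F statistic. Exact permutation of 2 against 2 libraries cannot go below p = 0.33, so library shares were given without a test. Intervals at 95% on counts cover counting error only.

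The design, the tests, the alternatives, 33 gene lists with 459 members (417 tested) and the rule for named genes were set before the data were examined. Lists covered the HBI1 network, hormones, cell wall, immunity and defence metabolism, photosynthesis, nutrients, light and clock, stress, and tissues of root, stomatal lineage and seed. List members were keyed by locus; 32709 loci of the count tables matched the TAIR10.1 gene table, 1 member was moved to another locus by its symbol and 11 were named by locus. Each list was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, two-sided, adjusted over the lists. Each was tested again with an estimated correlation and with fry, which tests a set against no change and not against other genes. With an estimated correlation camera rests on the 2 residual degrees of freedom, so hardly any list could pass. A miss there decides nothing about a list. The estimated correlations, uncertain on so few libraries, ran from -0.122 (brassinosteroid signalling) to 0.758 (cytokinin), with 0.568 for photosynthesis. Where members are correlated above the preset 0.01, the camera p with the preset is too small. HBI1 was left out of its own list's set test. Named genes were 11 genes fixed by name (HBI1, BEE1, IBH1, PRE1, PRE5, DWF4, CPD, IAA19, FRK1, WRKY29 and PR1), the 8 largest rises and 8 largest falls among called nuclear genes with a mean of at least 10 CPM, and up to 3 called members per list with the smallest adjusted p. A gene that this rule names in the ethylene list is counted in the totals but not reported here. Families were defined by symbol prefix with at least 8 tested members and compared with other genes that have a symbol by Fisher's exact test.

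Alternatives were DESeq2-style RLE factors, total counts without TMM, no low-count filter, a stricter filter of 1 CPM, DESeq2 1.42.0, limma-voom, limma-trend, the replicate number as a block, leaving out each library in turn, leaving out organellar and ribosomal RNA genes and HBI1, a 2-fold minimum, and a threshold of 0.01. Summing the HBI1-Ox libraries as 1 sample was added after seeing the data.

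Libraries of 1 group were compared by a chi-square test of each nuclear gene with at least 20 reads in the pair. The HBI1-Ox libraries agreed nearly within counting error; they were kept as 2 samples as the design had them, which does not show that they are independent. The procedure was tested on simulated data for HBI1-Ox against Col-0: 20320 genes were simulated, 200 of them changed, 21 in a changed list and 20099 unchanged, and the filter kept 20123. In this run 83% of the 2-fold and 61% of the 1.5-fold changes were recovered, and 8 of the 19902 unchanged genes kept were called. The 1 list with a simulated change was the only list called. The simulated libraries and genes were independent, with the same spread in both groups. In the data the pairs differed in spread (chi-square per gene 1.23 for HBI1-Ox, 7.77 for Col-0), so the run does not give the error rates there. Promoters were the 500 bp upstream of the gene in TAIR10.1 and were scanned on both strands for CACGTG, CATGTG and TTGACY, with AAACCCTA as a comparison. The logistic model and Fisher's test were run on simulated calls with a known odds ratio. Product descriptions were searched for 29 terms chosen after the data were seen; 3 of the patterns (ethylene response or AP2, thionin, germin) at first matched unrelated descriptions and were corrected after their first results had been seen, and the values given are those after the correction. Reads of close paralogs (such as GSTF6 and GSTF7, or CYP71A12 and CYP71A13) may be shared between them.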

Results

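RNA was sequenced from whole Arabidopsis thaliana seedlings grown for 5 days under constant light. The series set seedlings that overexpress HBI1, a basic helix-loop-helix (bHLH) transcription factor, beside the wild-type accession Col-0. The overexpressing line, HBI1-Ox, carries HBI1 fused to yellow fluorescent protein behind the 35S promoter of cauliflower mosaic virus, a strong promoter in most plant tissues. There were 2 libraries per group. Reads counted on genes came to 13068448 and 10785178 in Col-0 libraries 1 and 2, and to 19647745 and 14981824 in HBI1-Ox libraries 1 and 2. Chloroplast genes took between 0.185% and 0.604% of these reads and nuclear ribosomal RNA genes at most 0.458%. The comparison addresses how raised HBI1 expression alters the transcriptome, in a study of hormonal growth control and immunity. Only the HBI1-Ox line was set beside Col-0. Effects of HBI1 level therefore cannot be told apart from other differences of that line, for any gene below.

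HBI1 (AT2G18300; chromosome 2, 7952404 to 7954785, minus strand, TAIR10.1, with 3 annotated mRNA models of 6 to 7 exons) was the overexpressed gene and was examined first. Its normalised level was 99.3 and 84.6 CPM (read counts scaled to the normalised library size) in the Col-0 libraries and 1567 and 1509 CPM in the HBI1-Ox libraries. HBI1 rose by 4.06 ± 0.09 on the log2 scale (± standard error, as for every log2 change below), with an adjusted p of 1.7e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Reads were counted per gene, so transcripts of the introduced and of the native copy are not told apart. HBI1 is one of a network of bHLH proteins in which HLH partners without DNA binding hold growth-promoting factors in check. In that list of 22 tested members (HBI1 included), 11 rose, 3 fell and 8 did not pass the test; adjusted over the list alone, 11 rose and 5 fell. IBH1 (AT2G43060), an inhibitory partner of HBI1, rose by 1.02 ± 0.12, and its relatives IBL1 and AIF4 rose by 1.74 ± 0.07 and 1.41 ± 0.07. BEE1 (AT1G18400), a brassinosteroid-induced relative of HBI1, fell from 7.01 ± 0.52 to 2.83 ± 0.27 CPM (mean ± SD, n = 2 libraries each). PRE1 and PRE5, which encode HLH proteins that promote elongation, had log2 changes of -0.63 ± 0.28 and -0.72 ± 0.35 and did not pass the test, and their values depended on the Col-0 library used. Without Col-0 library 1 the log2 changes were -0.95 for PRE1 and -0.29 for PRE5, and without Col-0 library 2 they were -0.23 and -1.01. When a library is left out, the spread comes from the other group alone, so a pass or miss in such a setting is uncertain. As a set, without HBI1, the list lay above other genes but missed the threshold (camera adjusted p = 0.0563). It passed with scaling by total counts (camera adjusted p = 0.00246) and without the low-count filter (0.0371), but not with an estimated correlation (0.385). The fry test, which asks whether a set changed at all and not whether it differs from other genes, gave an adjusted p of 0.00877. Counting HBI1, 6 members were higher and 1 lower with the HBI1-Ox libraries summed as 1 sample (an alternative chosen after seeing the data), against 4 and 1 without HBI1-Ox library 1 and 5 and 1 without HBI1-Ox library 2, and 5 were lower without Col-0 library 2 or with scaling by total counts. BEE1 missed the threshold in these 3 settings (edgeR adjusted p = 0.0566, 0.0863 and 0.0588), and IBH1 without HBI1-Ox library 1 (0.0713).

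Across the transcriptome, 1693 genes were higher and 1452 lower in HBI1-Ox among 20320 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes made up 261 of the rises and 515 of the falls. The HBI1-Ox libraries differed from each other by little more than counting error, with a chi-square of 1.23 per nuclear gene against 7.77 between the Col-0 libraries, and 60 of 20123 genes told the first pair apart against 2340 of 20070 for the second. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Summing the HBI1-Ox libraries gave 306 higher and 273 lower genes. The counts were 242 and 187 without HBI1-Ox library 1, 289 and 222 without HBI1-Ox library 2, 3516 and 3009 without Col-0 library 1, and 3010 and 2773 without Col-0 library 2. When a library is left out, the lone library of its group is assumed to vary like the other group. Of 102 named genes that passed, 45 did not pass with the HBI1-Ox libraries summed, 52 without HBI1-Ox library 1, 50 without HBI1-Ox library 2 and 12 with DESeq2's Wald test. No gene called in both the full analysis and one of these had opposite directions. Of the calls, 53.8% were higher in HBI1-Ox. With scaling by total counts in place of TMM factors the median log2 change of all tested genes moved from -0.012 to -0.162, and 22.2% of the calls were then higher (995 higher, 3494 lower).

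**Figure D1:**
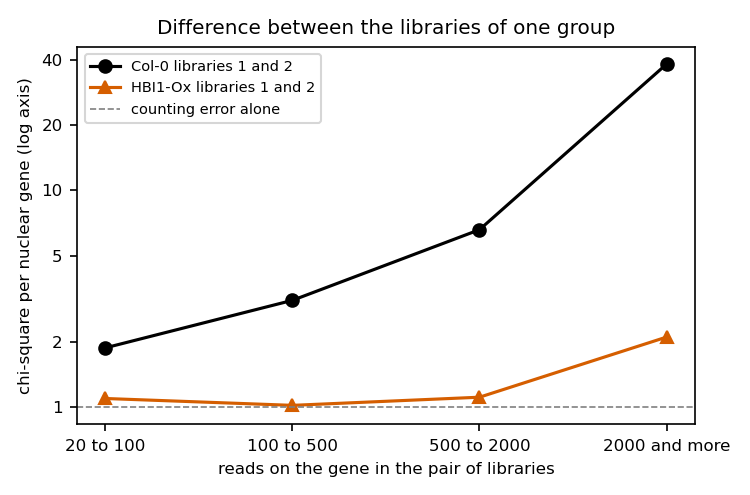
Chi-square per nuclear gene between the 2 libraries of a group (vertical log axis) by the number of reads on the gene in the pair (horizontal axis), with circles for Col-0, triangles for HBI1-Ox and a dashed line at the value that counting error alone gives. The HBI1-Ox pair lies at 1.02 at 100 to 500 reads and at 2.101 from 2000 reads, and the Col-0 pair at 3.11 and 38.2.

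The largest rises among nuclear genes with at least 10 CPM on average were led by AT3G01345, a gene of unknown function, which had 5 and 6 reads in the Col-0 libraries and 2871 and 2290 in the HBI1-Ox libraries (log2 change 8.46 ± 0.12). AT1G49570, which encodes a class III peroxidase, rose by 4.69 ± 0.18. AT5G38940, of the cupin superfamily, rose by 2.90 ± 0.14. The lipid transfer protein genes AT2G37870 and LTP3 rose by 2.84 ± 0.08 and 2.80 ± 0.15. ASN1, a glutamine-dependent asparagine synthetase that is typically expressed under carbon limitation, rose by 2.50 ± 0.10, and the glycosyl hydrolase gene AT3G19620 by 2.34 ± 0.11. These 7 genes and HBI1 all had adjusted p at or below 0.0102 with the HBI1-Ox libraries summed (edgeR quasi-likelihood test).

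The largest falls, among nuclear genes with the same minimum level, were led by a cytochrome P450 gene. CYP71A12 (AT2G30750; chromosome 2, 13099486 to 13101371, minus strand, TAIR10.1), of indole defence metabolism, had 408 and 351 reads in the Col-0 libraries and 2 in each HBI1-Ox library, which is 0.403% of its Col-0 level (95% exact counting interval 0.109% to 1.03%). CYP81F2 (AT5G57220), which modifies indole glucosinolates in immune responses, fell from 25.1 ± 1.3 to 1.01 ± 0.06 CPM. The glutathione S-transferase genes GSTF7 (AT1G02920) and GSTF6 (AT1G02930) had log2 changes of -4.09 ± 0.11 and -3.73 ± 0.12, and both fell; they lie side by side and are similar in sequence, so their separate values are uncertain. AT3G16670, an extensin-family gene (-4.04 ± 0.30), the cutinase gene CDEF1 (-3.85 ± 0.17), the defensin-like gene AT1G13609 (-3.30 ± 0.16) and BHLH100, a regulator of iron uptake (-2.88 ± 0.38), also fell. BHLH100 missed the threshold with the HBI1-Ox libraries summed (edgeR adjusted p = 0.0542), where the other 7 genes had adjusted p at or below 0.0161, and its log2 change was -2.22 without Col-0 library 1.

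**Figure D2:**
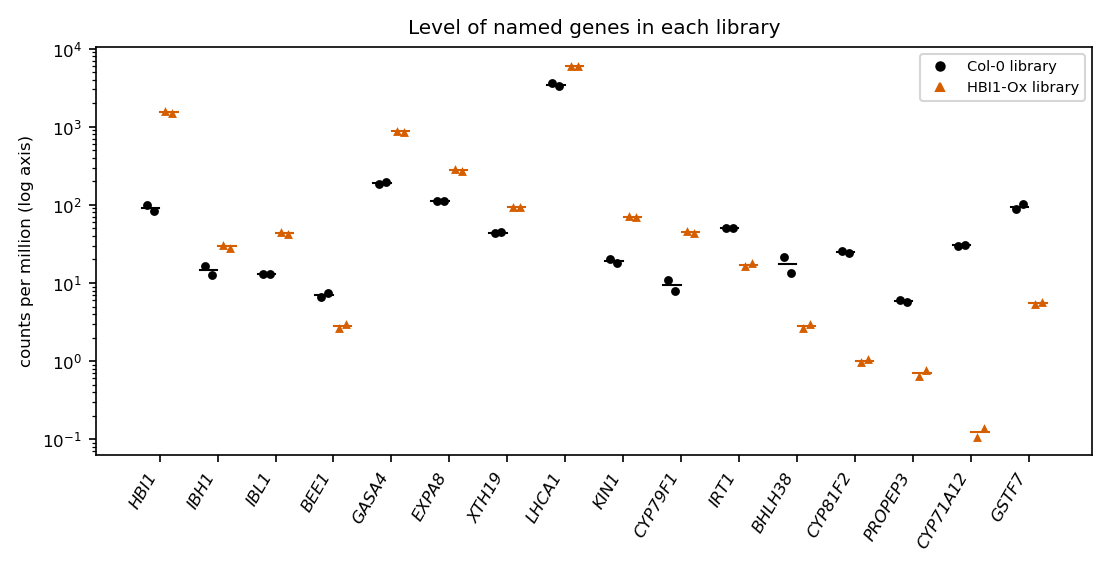
Level of 16 of the named genes in each library, in CPM on a log axis, with circles for Col-0 libraries, triangles for HBI1-Ox libraries and a horizontal bar at the mean of each pair. HBI1 stands at 1567 and 1509 CPM in HBI1-Ox against 99.3 and 84.6 CPM in Col-0, and CYP81F2 at 0.97 and 1.05 CPM against 26.0 and 24.1 CPM.

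In lists of pattern-triggered immunity, the response to microbial molecules, more genes fell than rose. Of 20 tested response genes 10 fell, none rose and 10 did not pass; adjusted over the list alone, 16 fell and 1 rose. Besides CYP81F2, the elicitor peptide precursor gene PROPEP3 fell from 5.88 ± 0.35 to 0.71 ± 0.09 CPM, and CML37, a calmodulin-like gene, had 46 and 33 reads in Col-0 against 5 and 3 in HBI1-Ox, 7.73% of its Col-0 level (95% exact counting interval 3.23% to 16.0%). WRKY29, a factor induced by flagellin, had a log2 change of -1.02 ± 0.20 and fell. FRK1, a classic marker of flagellin perception, had 5 and 7 reads in Col-0 and 13 and 10 in HBI1-Ox, and was left out by the low-count filter; in the 3 settings that kept it, it did not pass (edgeR adjusted p = 0.611 without that filter, 0.844 without Col-0 library 1 and 0.39 without Col-0 library 2). The response list stood below other genes (camera adjusted p = 1.33e-05; adjusted p = 0.385 with an estimated correlation). Among 9 tested receptor and kinase genes, 1 fell, the oxidase gene RBOHD (-0.72 ± 0.17), and 8 did not pass; adjusted over the list alone, 6 fell and 1 rose. The receptor list stood below other genes as well (camera adjusted p = 0.0234; adjusted p = 0.569 with an estimated correlation), but not without Col-0 library 2 (camera adjusted p = 0.301) or with scaling by total counts (0.0988). Tested against no change, it did not pass (fry adjusted p = 0.217). The list medians were higher in Col-0 library 2. Relative to the mean of the 4 libraries, the median response gene stood at 0.38 in Col-0 library 1 and 0.98 in Col-0 library 2 on the log2 scale. The median receptor gene stood at 0.04 and 0.36. Of the genes named above, RBOHD was higher in Col-0 library 2 (56.8 and 82.8 CPM in libraries 1 and 2). WRKY29 was higher in Col-0 library 1 (9.15 and 6.5 CPM, from 124 and 75 reads). CYP81F2 (26.0 and 24.1 CPM), PROPEP3 (6.13 and 5.64 CPM) and CML37 (46 and 33 reads) showed no clear difference between these libraries. Lower response genes numbered 4 with the HBI1-Ox libraries summed, 3 without HBI1-Ox library 1, 4 without HBI1-Ox library 2, 18 without Col-0 library 1 and 14 without Col-0 library 2, and WRKY29 passed in none of the first 3 settings. Higher response genes numbered 1 without Col-0 library 1, 3 without Col-0 library 2 and 1 with DESeq2, and 1 receptor gene was higher without Col-0 library 1 or 2. No receptor gene was lower in those 3 settings with fewer or summed HBI1-Ox libraries, against 6 without Col-0 library 1 or with scaling by total counts and 3 without Col-0 library 2, where RBOHD had a log2 change of -0.43.

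Of 8 genes that make indole defence compounds, 6 fell and 2 did not pass, over all genes and adjusted over the list alone. Besides CYP71A12 they included CYP71A13, an enzyme of camalexin synthesis (-1.88 ± 0.15), and CYP79B3, which turns tryptophan into indole-3-acetaldoxime (157 ± 3 to 99.6 ± 2.3 CPM). The list stood below other genes (camera adjusted p = 7.04e-05; adjusted p = 0.385 with an estimated correlation). Aliphatic glucosinolate genes went the other way: 6 of 14 rose and 1 fell, and adjusted over the list alone 8 rose and 1 fell. CYP79F1 and CYP83A1, enzymes of the core pathway, rose by 2.25 ± 0.14 and 1.28 ± 0.16. MAM3, a chain-elongation enzyme, fell by 0.91 ± 0.11 on the log2 scale. This list stood above other genes (camera adjusted p = 0.00104; adjusted p = 0.467 with an estimated correlation); tested against no change, it did not pass (fry adjusted p = 0.0797). Lower indole genes numbered 3 with the HBI1-Ox libraries summed, 3 without HBI1-Ox library 1 and 2 without HBI1-Ox library 2, and 1 aliphatic gene was higher in each of these settings. MAM3 passed with the HBI1-Ox libraries summed but not without HBI1-Ox library 1 or 2, and 9 aliphatic genes were higher and 2 lower without Col-0 library 1.

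Of 11 tested salicylic acid genes, 4 fell and 7 did not pass; adjusted over the list alone, 5 fell. ALD1, an enzyme of pipecolic acid synthesis, had 27 and 19 reads in Col-0 and 6 and 3 in HBI1-Ox, 14.9% of its Col-0 level (95% exact counting interval 6.43% to 30.9%). WRKY70 fell from 7.69 ± 1.89 to 3.22 ± 0.22 CPM, and EDS5, a transporter needed for salicylic acid accumulation, fell from 17.1 ± 0.3 to 12.7 ± 0.3 CPM. PR1, the usual marker of this hormone, had 4 and 7 reads in Col-0 and 0 in both HBI1-Ox libraries, a count that allows up to 3 reads in each, and was left out by the low-count filter; without that filter it was lower (edgeR adjusted p = 0.0394). The list stood below other genes (camera adjusted p = 0.0103; adjusted p = 0.529 with an estimated correlation), but not without Col-0 library 2 (camera adjusted p = 0.241) or with scaling by total counts (0.0664). The fry test against no change did not pass either (adjusted p = 0.161). Only ALD1 was lower with the HBI1-Ox libraries summed, no gene was without HBI1-Ox library 1 or 2, and 8 genes were lower without Col-0 library 1. EDS5 did not pass DESeq2's Wald test (adjusted p = 0.209).

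Cell wall lists covered expansins, cellulose synthases and xyloglucan enzymes. Of 14 expansin genes, whose proteins loosen cell walls, 8 rose and 6 did not pass; adjusted over the list alone, 10 rose and 3 fell. EXPA8 rose from 111 ± 1 to 279 ± 10 CPM, EXPA16 by 1.16 ± 0.10 and EXPB1 by 0.86 ± 0.07 (log2). Of 8 cellulose synthase genes 6 rose and 2 did not pass, over all genes and adjusted over the list alone. The largest changes were in CESA8, CESA7 and CESA4, the subunits of the secondary wall (0.95 ± 0.08, 0.71 ± 0.09 and 0.50 ± 0.07). The camera adjusted p was 0.000248 for expansins and 6.97e-05 for cellulose synthases (adjusted p = 0.385 with an estimated correlation for each). Genes for xyloglucan endotransglucosylase/hydrolases, which cut and rejoin wall xyloglucan, moved both ways: 6 of 15 rose and 4 fell, and adjusted over the list alone 7 rose and 5 fell. XTH19 rose from 44.0 ± 0.9 to 94.4 ± 1.1 CPM, XTH17 by 0.87 ± 0.06 and XTH18 by 0.84 ± 0.07 (log2). The list as a set did not pass (camera adjusted p = 0.155) except without Col-0 library 1 (0.0102) or with scaling by total counts (0.0408); it was 0.58 with an estimated correlation, and fry, against no change, gave 0.0365. Summed HBI1-Ox libraries gave 3 higher expansin, 1 higher cellulose synthase and 4 higher xyloglucan genes and no lower one, and leaving out HBI1-Ox library 1 or 2 gave the same counts. Without Col-0 library 1 or 2, or with scaling by total counts, 3 expansin genes were lower, and 10 xyloglucan genes were higher without Col-0 library 1 and 7 lower without Col-0 library 2.

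The gibberellin list held as many falls as rises, and the brassinosteroid lists held genes that rose and genes that did not pass. GASA4 and GASA6, gibberellin-responsive genes of small secreted peptides, rose from 191 ± 10 to 879 ± 21 CPM and from 212 ± 15 to 749 ± 36 CPM, and GA3OX1, which makes active gibberellin, rose by 1.57 ± 0.11 on the log2 scale. In the gibberellin list 3 of 15 rose and 3 fell; adjusted over the list alone, 4 rose and 4 fell. The list did not pass as a set (camera adjusted p = 0.352) except without Col-0 library 1 (3.55e-05) or without Col-0 library 2 (6.2e-09); it was 0.56 with an estimated correlation, and fry, against no change, gave 0.0171. In brassinosteroid synthesis DWF4 and CPD rose by 0.74 ± 0.08 and 0.50 ± 0.06, and 8 of 10 genes did not pass; adjusted over the list alone, 2 rose and 1 fell. In brassinosteroid signalling the receptor gene BRI1 (0.43 ± 0.06), its inhibitor BKI1 (0.45 ± 0.08) and the kinase gene BIN2 (0.26 ± 0.06) rose and 4 of 7 did not pass, with the same 3 rises adjusted over the list alone. Neither list passed as a set (camera adjusted p = 0.128 for synthesis and 0.0576 for signalling), except signalling without the low-count filter (0.0375). With an estimated correlation signalling had 0.385, and fry, against no change, gave 0.031. Higher genes numbered 3 for gibberellin, 1 for synthesis and 0 for signalling with the HBI1-Ox libraries summed, without HBI1-Ox library 1 and without HBI1-Ox library 2, and no gibberellin gene was lower there. CPD passed in none of these settings, 5 synthesis genes were higher and 1 signalling gene lower without Col-0 library 1, 1 synthesis gene was lower without Col-0 library 2 or with scaling by total counts, BKI1 did not pass DESeq2's Wald test (adjusted p = 0.0836), and BIN2 did not pass with scaling by total counts (edgeR adjusted p = 0.18).

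In the auxin, cytokinin and ethylene lists more genes fell than rose. Of 22 auxin response genes 8 fell, 2 rose and 12 did not pass; adjusted over the list alone, 12 fell and 2 rose. DFL1, which conjugates auxin to amino acids, had a log2 change of -0.95 ± 0.08 and IAA3, an auxin signalling repressor, one of -0.53 ± 0.07, and both fell, while IAA7 rose by 0.39 ± 0.05. IAA19 had a log2 change of -0.48 ± 0.14 and did not pass (edgeR adjusted p = 0.0611), except without Col-0 library 1 (0.00255), without Col-0 library 2 (0.0304), without the low-count filter (0.0297) or with scaling by total counts (0.0238). The auxin list stood below other genes (camera adjusted p = 0.0138; adjusted p = 0.385 with an estimated correlation), but not without Col-0 library 1 (0.0616), without Col-0 library 2 (0.0558) or with scaling by total counts (0.0721). Of 8 tested type-A response regulators, which cytokinin induces, 5 fell, over all genes and adjusted over the list alone. They included ARR4 (-0.79 ± 0.13), ARR6 (-0.63 ± 0.13) and ARR7 (-2.61 ± 0.51), the last with 8.27 CPM in Col-0 library 1 and 23.3 CPM in Col-0 library 2 (log2 change -3.19 without Col-0 library 1 and -1.71 without Col-0 library 2; limma-voom adjusted p = 0.0538). The cytokinin list had a camera adjusted p of 0.00273 (adjusted p = 0.529 with an estimated correlation), and fry, against no change, gave 0.188. Of 11 ethylene genes 6 fell, also adjusted over the list alone, among them ERF2 (-1.63 ± 0.21) and ACS4 (-2.17 ± 0.34). The ethylene list had a camera adjusted p of 0.00905 (adjusted p = 0.385 with an estimated correlation). Only 1 auxin gene and no cytokinin or ethylene gene was lower with the HBI1-Ox libraries summed, without HBI1-Ox library 1 and without HBI1-Ox library 2. Leaving out Col-0 library 1 gave 8 lower cytokinin genes, and leaving out Col-0 library 2 gave 13 lower auxin genes and 1 higher ethylene gene.

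Of 17 tested abscisic acid and cold genes 11 rose and 1 fell. Adjusted over the list alone, 12 rose and 2 fell. The member that fell over all genes was CBF3 (-2.50 ± 0.43), named after its values were seen. It had 15 and 12 reads in Col-0 and 3 in each HBI1-Ox library. No member of the list was lower with DESeq2's Wald test. KIN1, a small hydrophilic protein gene of cold and drought, rose from 19.1 ± 1.5 to 70.6 ± 2.3 CPM. RD29B, a standard abscisic acid marker, rose by 1.84 ± 0.10 and RD22 by 1.02 ± 0.05. The list stood above other genes (camera adjusted p = 6.95e-06; adjusted p = 0.385 with an estimated correlation). Of 17 jasmonate genes 5 rose and 1 fell; adjusted over the list alone, 5 rose and 5 fell. JAZ3, a signalling repressor, and AOS, a synthesis enzyme, rose by 0.93 ± 0.08 and 0.80 ± 0.08, and VSP1, a storage protein gene, fell by 1.12 ± 0.12 on the log2 scale. The jasmonate list's median and mean changes were negative (-0.39 and -0.18) while its set test pointed up and did not pass (camera adjusted p = 0.656). Higher abscisic acid genes numbered 7 with the HBI1-Ox libraries summed, 5 without HBI1-Ox library 1 and 6 without HBI1-Ox library 2, and 5 were lower without Col-0 library 1. In each of the first 3 settings 2 jasmonate genes were higher, and lower jasmonate genes numbered 1, 0 and 1, against 8 without Col-0 library 1 and 5 without Col-0 library 2. Without Col-0 library 1 the jasmonate set test pointed down (camera adjusted p = 0.284).

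Most tested photosynthesis genes of the nucleus rose, while 4 of 13 root tissue genes fell and none rose (1 rose without Col-0 library 2); the shares of green tissue and root in the seedlings were not measured. Of 21 genes for light-harvesting proteins, photosystem subunits and Rubisco, 17 rose and 4 did not pass; adjusted over the list alone, 19 rose. LHCA1, a light-harvesting protein of photosystem I, rose from 3457 ± 165 to 5986 ± 108 CPM, and LHCB2.1 and LHCB2.2 by 0.83 ± 0.05 and 0.87 ± 0.05. Reads of near-identical copies (LHCB2.1 and LHCB2.2, the LHCB1 genes and the RBCS genes) could be divided between them by the counting. The list had a camera adjusted p of 8.67e-16 with the preset correlation of 0.01 (adjusted p = 0.385 with an estimated correlation, here 0.568). If its members are correlated above the preset, the first of these p-values is too small. In chlorophyll synthesis 6 of 12 rose and 1 fell, or 7 and 1 adjusted over the list alone. HEMA1, the first committed enzyme, rose by 0.96 ± 0.05, GUN5, a subunit of magnesium chelatase, by 0.61 ± 0.05 and CAO, which makes chlorophyll b, by 0.55 ± 0.06. The chlorophyll list had a camera adjusted p of 0.00549 (adjusted p = 0.467 with an estimated correlation). Of 11 genes that remove reactive oxygen species 5 rose, or 7 adjusted over the list alone. They included CAT2, a catalase of peroxisomes, from 769 ± 25 to 1386 ± 8 CPM, FSD1 (0.82 ± 0.07) and CAT1 (0.41 ± 0.07). This list had a camera adjusted p of 0.00106 (adjusted p = 0.385 with an estimated correlation). Higher photosynthesis genes numbered 4 with the HBI1-Ox libraries summed, 5 without HBI1-Ox library 1 and 6 without HBI1-Ox library 2, with 1 chlorophyll gene and 2 genes of reactive oxygen removal in each case. Leaving out Col-0 library 1 gave 1 lower photosynthesis gene and 1 lower gene of reactive oxygen removal, and leaving out Col-0 library 2 gave 1 lower gene of reactive oxygen removal and 3 lower chlorophyll genes, and CAT1 did not pass DESeq2's Wald test (adjusted p = 0.064).

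Of 11 tested iron genes 9 fell and 1 rose; adjusted over the list alone, 10 fell and 1 rose. IRT1, the main iron transporter of the root surface, fell from 50.6 ± 0.7 to 17.2 ± 1.0 CPM. BHLH38 and BHLH100, regulators induced by iron shortage, had log2 changes of -2.63 ± 0.26 and -2.88 ± 0.38, and both fell. Several of these genes act mainly in roots; 4 of 13 root tissue genes fell and none rose (1 rose without Col-0 library 2), while 2 of 12 root hair genes rose and none fell, and the share of root in the seedlings was not measured. The member that rose, FER1 (1.19 ± 0.11), encodes ferritin, which stores iron and is induced when iron is plentiful. The list had a camera adjusted p of 1.79e-05 (adjusted p = 0.385 with an estimated correlation). Of 13 nitrate genes 4 fell and 1 rose, over all genes and adjusted over the list alone. BT2 fell from 301 ± 8 to 184 ± 8 CPM, NRT3.1, a partner of nitrate transporters, fell from 11.6 ± 0.5 to 5.50 ± 0.52 CPM, and the transporter gene NRT1.1 rose by 0.44 ± 0.05. The nitrate list had a camera adjusted p of 0.0276 (adjusted p = 0.56 with an estimated correlation), and did not pass without Col-0 library 2 (0.381) or with scaling by total counts (0.0814); fry, against no change, gave 0.203. Of 10 phosphate genes 3 rose and 1 fell; adjusted over the list alone, 7 rose and 1 fell. SQD2 (0.59 ± 0.07) and MGD2 (0.55 ± 0.11), which make lipids without phosphate, and the transporter gene PHT1;4 (0.68 ± 0.09) rose. The phosphate list had a camera adjusted p of 0.0149 (adjusted p = 0.385 with an estimated correlation), and did not pass without Col-0 library 1 (0.284) or 2 (0.227). Lower iron genes numbered 5 with the HBI1-Ox libraries summed, 4 without HBI1-Ox library 1 and 5 without HBI1-Ox library 2; in each case 1 nitrate gene was lower and no phosphate gene passed. Without Col-0 library 1, 10 nitrate genes were lower and 2 higher, and 7 phosphate genes higher and 2 lower; without Col-0 library 2, 3 nitrate genes were higher, and MGD2 did not pass DESeq2's Wald test (adjusted p = 0.144) or scaling by total counts (edgeR adjusted p = 0.0534).

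Lists for light and clock responses changed little as sets. PIF4, PIF5 and HAT1, factors of growth in shade, rose by 1.22 ± 0.19, 0.57 ± 0.08 and 0.62 ± 0.10; in the shade and light list 3 of 13 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.385, or 0.56 with an estimated correlation; fry adjusted p against no change = 0.0454). In the clock list CCA1 (0.41 ± 0.07) and PRR7 (0.37 ± 0.09) rose and ELF3 fell (-0.46 ± 0.06); the other 9 of 12 did not pass, and adjusted over the list alone 3 rose and 3 fell (camera adjusted p = 0.713). In the flavonoid list TT7 rose (0.71 ± 0.15) and MYB111 fell (-1.09 ± 0.21) among 10 tested, with 1 rise and 2 falls adjusted over the list alone (camera adjusted p = 0.585). No gene of these lists passed with the HBI1-Ox libraries summed, without HBI1-Ox library 1 or without HBI1-Ox library 2. In the clock list 5 rose and 4 fell without Col-0 library 1 and 5 rose and 2 fell without Col-0 library 2, where PRR7 had a log2 change of 0.24; in the shade and light list 2 fell without either Col-0 library; in the flavonoid list 2 rose without Col-0 library 1 and 4 fell without Col-0 library 2, and its set test pointed up without Col-0 library 1 (camera adjusted p = 0.781). PRR7 and MYB111 did not pass DESeq2's Wald test (adjusted p = 0.1 and 0.094), and CCA1 and PRR7 did not pass with scaling by total counts (edgeR adjusted p = 0.0604 and 0.111).

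Lists for other tissues and for division were included as signs of a different make-up of the seedlings. Of 13 root tissue genes 4 fell, also adjusted over the list alone. PYK10, an abundant beta-glucosidase of roots, fell from 5619 ± 145 to 3462 ± 38 CPM, and CASP2 (-0.33 ± 0.06) and CASP4 (-0.61 ± 0.15) of the Casparian strip fell too. The root list missed the threshold (camera adjusted p = 0.0748), but passed without Col-0 library 1 (0.00129), Col-0 library 2 (0.00139) or HBI1-Ox library 1 (0.0428) and with the stricter filter (0.0473), and not with an estimated correlation (0.529). Of 12 root hair genes RHD2 (0.75 ± 0.07) and PRP1 (0.26 ± 0.06) rose, also adjusted over the list alone (camera adjusted p = 0.155). In the stomatal lineage SPCH, the factor that starts it, fell (-1.10 ± 0.23) and 9 of 10 genes did not pass, also adjusted over the list alone (camera adjusted p = 0.0531; 0.0378 with the HBI1-Ox libraries summed, 0.0413 without HBI1-Ox library 2, 0.0496 without the low-count filter, 0.0424 with the stricter filter, 0.385 with an estimated correlation and 0.0306 by fry against no change). CYCD3;1 was the 1 cell cycle gene of 10 that fell (-0.44 ± 0.09; camera adjusted p = 0.428), and SAUR14 was the 1 of 15 SAUR genes (-0.43 ± 0.07; camera adjusted p = 0.428), with the same counts adjusted over the list alone. In the seed list ABI3 fell (-2.05 ± 0.27), and SESA4, a seed storage albumin, fell from 14 and 10 reads to 2 and 0 (6.37% of its Col-0 level, 95% exact counting interval 0.729% to 25.6%); 6 of 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.428). RHD2 and both seed genes passed with the HBI1-Ox libraries summed, but no gene of the root tissue, stomatal, cell cycle or SAUR lists, and RHD2 alone passed without HBI1-Ox library 1 or 2. Without Col-0 library 1, 3 stomatal genes were lower, and without Col-0 library 2, 2 stomatal genes and 3 SAUR genes. Higher genes without Col-0 library 2 numbered 1 in each of the root tissue, SAUR and seed lists, and 1 SAUR gene was also higher without Col-0 library 1 and with RLE factors. CASP2, CASP4, PRP1, SPCH and CYCD3;1 did not pass DESeq2's Wald test (adjusted p = 0.166, 0.132, 0.28, 0.0525 and 0.115), nor PRP1 scaling by total counts (edgeR adjusted p = 0.242).

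Heat shock genes differed between the Col-0 libraries: of 8 tested, 5 were lower and 3 higher in Col-0 library 2 than in library 1. HSP70 stood at 821 CPM in Col-0 library 1, 80.3 CPM in Col-0 library 2, and 1037 and 1012 CPM in HBI1-Ox; it was singled out after its values were seen. Of 8 tested members, the small heat shock protein genes HSP17.6A (-3.01 ± 0.34) and HSP17.6II (-2.40 ± 0.52) fell and 6 did not pass; adjusted over the list alone, 3 fell. The list's median change was 0.25, its mean -0.52, and its set test pointed down without passing (camera adjusted p = 0.614). With scaling by total counts the set test pointed up (0.609). Without Col-0 library 1, which leaves Col-0 library 2 as the only wild-type library, it pointed up and passed (5.28e-17). HSP17.6A alone was lower with the HBI1-Ox libraries summed, no member was without HBI1-Ox library 1, and 1 was without HBI1-Ox library 2. Without Col-0 library 1, 4 members were higher and 3 lower, and without Col-0 library 2, 1 was higher and 4 lower; HSP17.6II did not pass DESeq2's Wald test (adjusted p = 0.0538).

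**Figure D3:**
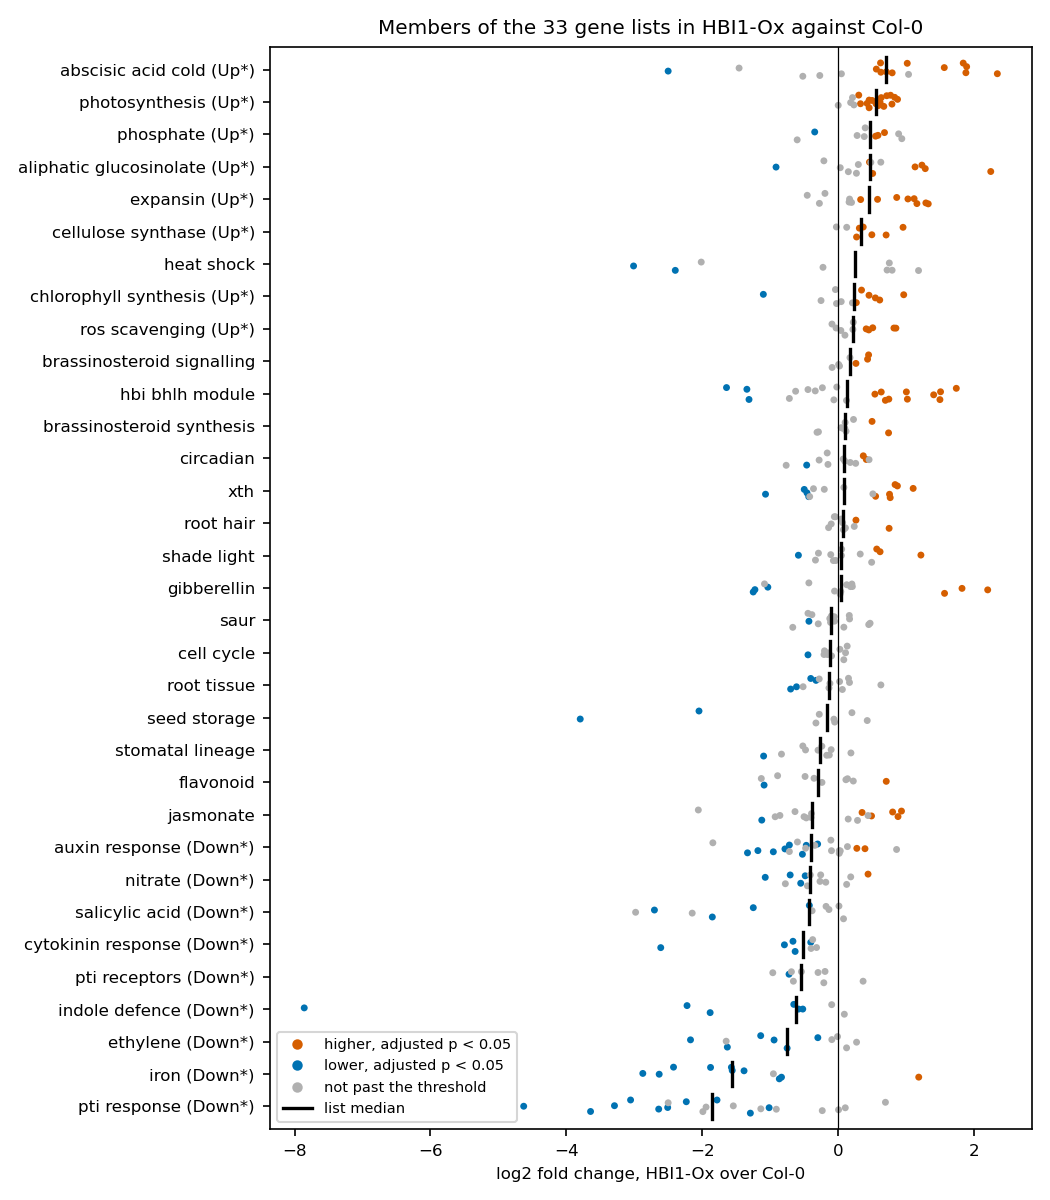
Log2 fold change (horizontal axis, HBI1-Ox over Col-0) of every tested member of the 33 gene lists (HBI1 itself left out), with 1 point per gene, orange for higher, blue for lower and grey for not past the threshold, and a black bar at each list's median. An asterisk with Up or Down marks the 17 lists that passed camera with the preset correlation of 0.01. None of them passed with an estimated correlation, where the lowest adjusted p was 0.385. That test had only 2 residual degrees of freedom, so hardly any list could pass it.

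Grouping genes by the family name in their symbol gave 11 departures among 62 tests of 31 families (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted). These tests take genes as independent, while genes of a family can change together, and all calls rest on the same 4 libraries. Their p-values therefore describe shares of genes and not evidence from replicates. Lower genes were frequent among CYP7-numbered cytochromes P450 (28 of 109, adjusted p = 6.2e-06) and, within these, symbols that start with CYP71 (12 of 44, 0.0056). They were also frequent among tau and phi class glutathione S-transferases (GSTU 8 of 23, 0.00572 and GSTF 4 of 10, 0.0432) and WRKY factors (12 of 51, 0.00974). No WRKY gene was higher (0.0362). Higher genes were frequent among arabinogalactan proteins (AGP 10 of 27, 0.0056), fasciclin-like arabinogalactan proteins (FLA 6 of 14, 0.0155), plasma membrane aquaporins (PIP 8 of 19, 0.00572), XTH (9 of 26, 0.00974) and alpha-expansins (EXPA 6 of 17, 0.0388). After scaling by total counts the tests of CYP71 (adjusted p = 0.107), FLA (0.612) and higher WRKY genes (0.318) no longer passed. Nor did CYP71 (0.0733), EXPA (0.0733) and GSTF (0.0865) without the low-count filter, or higher WRKY genes with calls from DESeq2 (0.133). Summing the HBI1-Ox libraries left 4 tests past the threshold, those of CYP7 (10 lower), CYP71 (5 lower), GSTF (4 lower) and XTH (5 higher). The same 4 passed without HBI1-Ox library 1, and all but CYP71 (adjusted p = 0.051) without HBI1-Ox library 2. CYP71 (0.333), EXPA (0.22) and GSTF (0.0608) did not pass without Col-0 library 1, nor higher WRKY genes (0.07) without Col-0 library 2.

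The authors' deposited table of this comparison lists 600 genes as higher and 656 as lower in HBI1-Ox. It rests on the same libraries and is no independent evidence. Of its genes 1252 were tested here, and all had the same sign; across these genes, which are not replicates, Spearman's rho of the log2 changes was 0.9999. The edgeR test called 1237 of them in the same direction, 596 higher and 641 lower, where independent lists would share 49.99 and 46.59. In the authors' deposited table HBI1 has a log2 change of 4.08, AT3G01345 one of 8.49 and CYP71A12 one of -7.92. The smallest absolute log2 change in the authors' deposited table is 0.559, and 410 genes called here with at least that change are outside it. On summed HBI1-Ox libraries, 560 of the table's genes were called in the same direction, and without HBI1-Ox library 1 or 2 the counts were 422 and 497.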

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

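Summing the HBI1-Ox libraries was chosen only after the data were seen; the other settings were planned. HBI1 rose in every setting that included it, with a log2 change of 3.95 to 4.20 when 1 library was left out. No gene called in the full analysis was called in the opposite direction in any setting. Of 102 named genes called, 52 missed the threshold without HBI1-Ox library 1, 50 without HBI1-Ox library 2, 45 with the HBI1-Ox libraries summed, 12 with DESeq2 and 5 with scaling by total counts. Where a setting below changed a result, the cause was not tested, except that a 2-fold minimum or a stricter threshold leaves fewer calls by construction. Scaling by total counts gave 995 higher and 3494 lower genes, and DESeq2's Wald test gave 1150 and 844. A 2-fold minimum left 261 higher and 515 lower genes, 6 family tests and 605 genes shared with the authors' deposited table. A threshold of 0.01 left 709 higher and 519 lower. With the HBI1-Ox libraries summed there were 306 higher and 273 lower genes, 4 family tests and 560 shared genes. Leaving out 1 library at a time gave 242 to 3516 higher genes, 187 to 3009 lower genes, 3 to 15 family tests and 422 to 1248 shared genes. The direction depended on the group: without a Col-0 library there were more calls (3516 and 3010 higher), and without an HBI1-Ox library fewer (242 and 289 higher); the lone library was assumed to vary like the other group. Set tests turned direction in 4 lists: heat shock with scaling by total counts (camera adjusted p = 0.609), clock genes with fry (0.907), and flavonoid, heat shock and jasmonate genes without Col-0 library 1. Leaving out 1 library gave camera adjusted p of 0.511 to 0.781 for flavonoid, 5.28e-17 to 0.554 for heat shock and 0.284 to 0.718 for jasmonate genes. Of the 17 lists called, camera called all 17 with RLE factors, without the low-count filter, with the stricter filter and with the replicate block. It called 13 of them with scaling by total counts. Without Col-0 library 2 the auxin, nitrate, phosphate, receptor and salicylic acid lists no longer passed. The auxin and phosphate lists also failed without Col-0 library 1. With fry, which tests against no change, 12 of the 17 were called. Camera with an estimated correlation called 0, but it had only 2 residual degrees of freedom and could hardly pass any list. The 4 lists that turned direction were not among the 17.

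The replicate block, with library numbers treated as paired, gave 1459 higher and 1337 lower genes, of which 1395 and 1229 were among the calls without it; PRP1 missed the threshold (edgeR adjusted p = 0.0613), the HBI1 network and stomatal lists passed (camera adjusted p = 0.0481 for each), and FLA and higher WRKY genes did not (Fisher adjusted p = 0.133 and 0.062). The deviations of same-numbered libraries had a correlation of 0.000376 across genes. The HBI1-Ox libraries differed by little more than counting error, so this value cannot tell whether same-numbered libraries were paired. The labels give no shared culture or day. Depth limits genes with few reads: FRK1 and PR1 were left out by the low-count filter, and without it PR1 was lower (edgeR adjusted p = 0.0394) on 4 and 7 reads in Col-0 against 0, while FRK1 did not pass (0.611).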

Other observations

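The product groups, the promoter tests on summed libraries, the simulation and the tests of the 3 patterns in the last paragraphs were chosen only after the results were seen; the 5 promoter tests on all 4 libraries were written with the gene calls already known but before any promoter was searched. The bounds for the tests of read content and of one RNA sample were rewritten after their values were seen. Product descriptions in the TAIR10.1 annotation were searched for 29 terms, in both directions, and 21 of 58 tests passed (Fisher's exact test, Benjamini-Hochberg adjusted). As for the families, genes are not replicates and can change together, so these p-values describe shares of genes only. Of 64 tested genes described by photosystem or chlorophyll a terms, 44 were higher (adjusted p = 8.58e-31). Higher genes were also frequent among arabinogalactan proteins (17 of 45, 8.87e-07), which sit at the cell surface, aquaporins (11 of 27, 5.63e-05), which pass water across membranes, tubulins (10 of 28, 0.000426), dehydrins and late embryogenesis proteins (16 of 73, 0.00149), extensins and proline-rich proteins (27 of 162, 0.00243), lipid transfer proteins (14 of 67, 0.00482) and pectin enzymes (19 of 124, 0.0378). They were rare among ribosomal proteins (4 of 317, 6.92e-07), heat shock proteins (1 of 93, 0.0143) and chaperones (3 of 127, 0.0274). Class III peroxidases, enzymes of the cell wall and apoplast, held many of both kinds (15 of 56 higher, 0.000375; 10 lower, 0.0201).

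Lower genes were frequent among cytochromes P450 (41 of 177, adjusted p = 6.12e-10), thionins and defensins (8 of 16, 5.63e-05), MLP-like proteins (5 of 8, 0.000605), glutathione S-transferases (12 of 48, 0.00068), bHLH factors (18 of 94, 0.00068), WRKY factors (12 of 52, 0.00136), germins (8 of 31, 0.00482) and calcium-binding proteins (17 of 108, 0.00778).

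These groups were tested again with scaling by total counts, with DESeq2, without each library and with the HBI1-Ox libraries summed. In all of these, tests passed for photosystem genes (summed: 6 higher, adjusted p = 0.00421), lipid transfer proteins (6 higher, 0.00462), higher peroxidases (7, 0.000433), P450 genes (15 lower, 1.31e-06), MLP-like proteins (4 lower, 6.67e-05) and glutathione S-transferases (6 lower, 0.000682). Dehydrins failed only without Col-0 library 1 (0.181). With summed libraries the other 14 did not pass: arabinogalactan proteins (0.35), aquaporins (0.168), tubulins (1), extensins (0.14), pectin enzymes (0.141), ribosomal proteins (0.24), heat shock proteins (0.673), chaperones (0.523), lower peroxidases (0.0523), defensins (0.088), bHLH factors (0.0548), WRKY factors (0.803), germins (0.0548) and calcium-binding proteins (0.397). Without HBI1-Ox library 1 these did not pass either, except bHLH factors (0.0152), and without HBI1-Ox library 2 none of them did. Leaving out Col-0 library 1, lower peroxidases (0.651), germins (0.0802), pectin enzymes (0.105) and chaperones (0.19) did not pass, and heat shock proteins turned to frequent higher genes (31 of those tested, 0.000529). Without Col-0 library 2, calcium-binding proteins (0.158) and heat shock proteins (0.206) did not. Scaling by total counts ended 8 passes: tubulins (0.752), germins (0.348), extensins (0.234), heat shock proteins (0.164), pectin enzymes (0.119), lower peroxidases (0.082), calcium-binding proteins (0.0776) and chaperones (0.0643). DESeq2 ended 2: heat shock proteins (0.099) and defensins (0.0655).

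The hypothesis was that genes called in HBI1-Ox carry bHLH binding motifs within 500 bp upstream more often than genes not called, in a logistic model with promoter GC content and expression. The G-box CACGTG was more frequent in promoters of higher genes (14.4% against 9.9%, odds ratio 1.64, 95% interval 1.4 to 1.92) and of lower genes (10.3%, odds ratio 1.22, 1.02 to 1.46). The E-box CATGTG was more frequent in promoters of higher genes (29.5% against 20.6%, odds ratio 1.74, 1.55 to 1.95), while for lower genes the odds ratio of 0.905 (0.788 to 1.04) leaves the question open. The W-box TTGACY, which WRKY factors bind, was more frequent in promoters of lower genes (51.7% against 44.6%, odds ratio 1.35, 1.21 to 1.51). A comparison motif, AAACCCTA, was rarer in promoters of higher genes (odds ratio 0.575, 0.439 to 0.754), also on calls from summed HBI1-Ox libraries (0.271, 0.111 to 0.658). The model thus also separates genes by a motif outside the hypothesis, and motif presence does not show binding. Its intervals take genes as independent. On calls from summed HBI1-Ox libraries the odds ratios were 2.52 (1.99 to 3.19) for CATGTG and 1.46 (1.04 to 2.05, adjusted p = 0.0586) for CACGTG in higher genes, 0.98 (0.64 to 1.5) for CACGTG in lower genes, and 1.54 (1.21 to 1.96) for TTGACY in lower genes.

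The HBI1-Ox libraries differed little beyond counting error. A single library deposited under 2 names is argued against by the share of reads on the ribosomal RNA locus AT3G41768, which was 1.8 times (95% counting interval 1.77 to 1.83) as high in HBI1-Ox library 1 as in library 2. Whether they are 2 libraries made from one RNA sample stays open, as do closely matched cultures: the chi-square per gene was 1.017 to 1.109 below 2000 reads, a restatement of the pattern, and 2.101 at 2000 reads or more, with 68 genes apart, where the Col-0 pair had 38.22. In 20 simulations of 20320 unchanged genes with the Col-0 spread, a median of 1009.5 genes (896 to 1100) lay at or below the p of the last call, 0.00773, if both HBI1-Ox libraries came from one culture, against 165 (139 to 225) with 4 separate cultures. Benjamini-Hochberg calls numbered 14 (2 to 41) and 8.5 (3 to 28) there, and 33.5 (11 to 56) with summed libraries. Differences between cultures were simulated separately for each gene. In the data, groups of genes such as the heat shock and immune response lists had medians that differed between the Col-0 libraries. The simulated calls therefore do not give the number of false calls in the data.

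Col-0 library 2 differed from Col-0 library 1 in heat shock genes, with a median log2 gap of 2.05 over 8 list members, of which 5 were lower and 3, with few reads, higher. A label exchanged between Col-0 and HBI1-Ox is argued against by HBI1, at 0.852 of its level in Col-0 library 1. Ribosomal and chloroplast read content of the library is argued against by the HBI1-Ox pair, which differed 1.81-fold in ribosomal RNA and 2.38-fold in chloroplast share (1.9-fold and 1.73-fold for Col-0) but by a median log2 of 0.03 in heat shock genes (members -0.471 to 0.569), where the Col-0 gap scaled to these shares would be -1.89 or -3.22; HBI1-Ox library 1 also had more of both shares than Col-0 library 2. Growth or harvest of that culture stays open, as 0 label fields other than the title differ between the Col-0 libraries. The immune gene WRKY33 (68.9 and 180 CPM in Col-0, 21.7 and 21.9 CPM in HBI1-Ox) was also higher in Col-0 library 2. So was the nitrate reductase gene NIA1 (672 and 1287 CPM in Col-0, 571 CPM in both HBI1-Ox libraries). Both were named after their values were seen. The median immune response gene was higher there too (0.38 and 0.98 relative to the mean of all libraries, log2). Not every immune gene was higher there. WRKY29 was higher in Col-0 library 1 (9.15 and 6.5 CPM), and CYP81F2 showed no clear difference (26.0 and 24.1 CPM).

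CYP71A12 was almost without reads in HBI1-Ox. Loss of a segment that includes its neighbours at higher coordinates is argued against by AT2G30766, which kept 25% of its Col-0 level, and CYP71A13, which kept 27.2%. These genes overlap on opposite strands, so their reads may be shared. Both start beyond the end of CYP71A12 (13107583 and 13109909 against 13101371). No gene on its other side was tested, so a loss that reaches only that way stays open. Change of the DNA at CYP71A12 alone cannot be told apart from lower transcription: 4 reads remained against 759 in Col-0, and similar genes such as CYP71A13 (97 reads in HBI1-Ox) could supply a few. Lower transcription with the other indole defence genes, the biological alternative that the design gives, was not tested separately.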
